A study of Homo sapiens with 2 samples.

How the data were processed

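RNA was measured in extracellular vesicles of LAD2, an established human mast cell line, in 2 libraries of 1 group. Per the labels' protocols, the cells grew in SP34 medium with stem cell factor under 5% CO2 at 37 °C, the vesicles were collected after 4 days, RNA was extracted with a Qiagen micro-scale kit, and libraries were made with an NEB NextUltra kit that the labels call a DNA library kit. The labels do not state whether that kit marks the strand of the RNA. FastQC 0.11.5, STAR 2.6.1a and the genome build hg38 are named in the submitters' processing notes. The counting tool, its strand setting, the annotation, the transform and whether the mates of a read pair were counted separately are not given in the sources used here.

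The authors deposited 1 value per gene and library, named as counts, but the deposited values are on a log2 scale: they hold fractions, and 1029 of 14467 genes lie below 0 in each library. The base was settled from the data: 2 to the power of the lowest values falls on even steps, and for genes with reads in 1 library alone the largest gap to a whole step was 0.071 of a step in replicate 1 and 0.046 in replicate 2. Both libraries hold the same 14467 genes and 4738 distinct values each. The difference between the libraries narrows towards 0 at low values, as it does after a regularised log transform, so the values were taken as normalized and shrunken. The spread over all genes, given as the SD of the difference divided by the square root of 2, was 0.0109 for means up to 2 and 0.248 for means above 10. The SD of low genes therefore understates their replicate error. Depth is not given in the sources used here. From the steps, 1 read was worth 0.835 linear units in replicate 1 and 1.16 in replicate 2, which puts the counted reads at about 2100000 in replicate 1 and 1600000 in replicate 2. Of the genes with reads in 1 library alone, 77.3% and 80.5% lay on even steps. If the mates of a pair were counted separately, the number of sequenced fragments would be lower than these figures. These are estimates, no counts were rebuilt from them, and no counting interval is given.

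The tests fixed before the data were examined assumed counts. On log2 values a count model, effective library sizes, an exact test of the counts of each gene, a chi-square check for duplicated libraries, thinning to equal depth and binomial intervals could not be used. The threshold of 10 counts became a linear value, 2 to the power of the deposited value, of at least 10 in both libraries, called detected below. Replicate error was the SD of the log2 difference divided by the square root of 2, the form fixed for values that are not counts. Genes differing between the libraries were counted at 2-fold or more, with no p-value. Shares are shares of the summed linear values. Whether 1 library had been deposited a second time was checked only by counting identical values. Comparisons of the 2 libraries describe these libraries and no condition.

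Before the data were examined, 45 gene lists were fixed, 39 by symbol and 6 by name pattern. The level of a list was the percentile of the median of its members with a value among 10000 random lists of the same size drawn from detected genes, for lists with at least 5 such members. Percentiles above 98 or below 2 were said to stand apart. Members below the detection threshold stayed in the list while the random lists held none, so this design places lists with many low members low by construction. The percentile against all genes with a value, also fixed before the data were examined, is therefore printed beside it. The difference of a list between the libraries was the percentile of its median log2 difference among 10000 random lists matched on mean level in 20 bins, for lists with at least 5 detected members. These percentiles describe the libraries and are no test across replicates.

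Genes named by rule were the 10 of highest mean, the 20 of highest mean that were neither mitochondrial nor cytosolic ribosomal protein genes, up to 4 members of highest value per list, the mast cell list members that did not reach the detection threshold, and up to 5 genes per direction with the largest ratio among genes differing 2-fold with a linear mean of at least 20. A few genes that this rule names are not reported here. Where examples are given, they were taken from the highest members of a list. Opposite-strand partners, the members of the 4 lists that go against the majority and any gene outside this rule were chosen after their values were seen. Symbols came from a table of gene identifiers, and 11066 of 14467 identifiers had one. Gene positions, types and exons came from GENCODE 29 on GRCh38, which is the build hg38, and 13733 identifiers had a model there. An opposite-strand partner shares at least 1 exonic base with the gene on the other strand. TALAM1 and MALAT1 positions came from the RefSeq annotation of the same build. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

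The list percentiles were tested on simulated data made from the deposited values. Against detected genes, 94.5% of 200 random lists of 20 genes with no shift, drawn from 14467 genes, were set apart, 0 of them as high, so a low call against detected genes does not tell a list from a random one. Of 10 lists raised by 3 log2 units, 0 were set apart there. Against all genes with a value, 2.5% of 200 random lists of 20 genes with no shift among 14467 genes were set apart by level. Of 10 lists of 20 genes raised by 1, 2 or 3 log2 units, 3, 8 and 10 were set apart against all genes, so a list that is higher by 1 log2 unit was mostly missed. For differences between the libraries among 6576 detected genes, 5.0% of 200 unshifted lists were set apart, and 10 of 10 lists lowered by 1 log2 unit were recovered. There the differences were first shuffled over the genes, which removes their dependence on level. Alternatives covered the detection threshold, the random-list background, a pseudocount, exonic length, the scaling and leaving out each replicate. Those chosen after seeing the data were all on strand and antisense genes, the pseudocounts of 1 and 5, list members limited to detected genes, the median mitochondrial difference, and the count of 2-fold genes without mitochondrial genes or at a linear value of at least 50.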

Results

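RNA sequencing covered extracellular vesicles, the membrane-bound particles that cells release, of LAD2, a human mast cell line grown with stem cell factor. The series concerns messenger RNA that mast cells pass to colorectal cancer cells in such vesicles, and these libraries address which RNA the vesicles hold. The 2 libraries, replicates 1 and 2, formed 1 group, so the comparisons were between genes within the libraries and between the 2 libraries. The labels do not say that the replicates came from separate cultures, so the spread between them may be technical. Values were present for 14467 genes, with a median log2 value of 3.09 in replicate 1 and 3.04 in replicate 2 and a maximum of 16.85 and 16.24. Detected genes numbered 6727 in replicate 1, 6613 in replicate 2 and 6576 in both. Gene values below are mean log2 ± SD of the 2 libraries (n = 2), and the SD is shrunken at low values. Read depth was estimated at about 2100000 reads in replicate 1 and 1600000 in replicate 2.

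The highest value belonged to TALAM1, a non-coding RNA transcribed from the strand opposite MALAT1, at 16.54 ± 0.43. TALAM1 lies on chromosome 11 from 65499312 to 65507432 (GRCh38) and shares 7205 genomic bases with MALAT1, a nuclear long non-coding RNA, which stood 13.75 log2 units lower at 2.79 ± 0.04. ENSG00000273149 (15.70 ± 0.43; chromosome 13, 45340039 to 45341183) followed, an antisense gene sharing 588 exonic bases with TPT1, a translationally controlled growth protein, at 4.30 ± 0.03. ENSG00000269968 (15.57 ± 0.23; chromosome 12, 6537794 to 6538370) lies opposite the glycolytic gene GAPDH at 5.11 ± 0.00. BEST1, an ion channel of the retinal pigment epithelium, had 15.41 ± 0.12 and shares 1267 exonic bases with FTH1, the ferritin heavy chain, at 6.03 ± 0.01. MRNIP had 15.32 ± 0.24 and its opposite-strand partner SQSTM1, an autophagy receptor, 8.68 ± 0.20. VIM-AS1 stood at 15.05 ± 0.26 and VIM, the intermediate filament vimentin, at 8.70 ± 0.10. ENSG00000265401 had 15.05 ± 0.35 and the ubiquitin gene UBB 3.46 ± 0.00. TUBA1B-AS1 had 14.85 ± 0.20 and the tubulin gene TUBA1B 5.62 ± 0.06. The 10 highest genes were completed by ENSG00000272540 at 14.50 ± 0.29, opposite the tubulin gene TUBB at 5.08 ± 0.07, and ENSG00000234961 at 14.20 ± 0.03, also opposite VIM. Together these 10 genes held 23.6% ± 0.691 of the summed linear value (n = 2), and TALAM1 alone held 6.73% in replicate 1 and 4.18% in replicate 2.

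**Figure D1:**
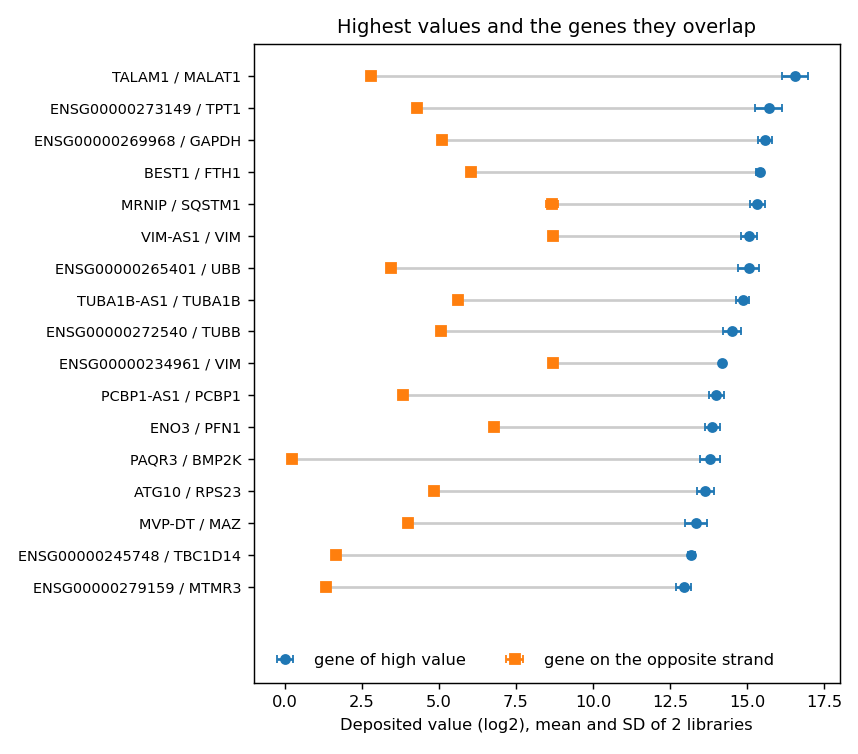
Mean deposited log2 value of the highest genes (circles) and of the genes they overlap on the opposite strand (squares), with SD of 2 libraries as error bars. TALAM1 at 16.54 and MALAT1 at 2.79 are at the top. Every circle lies to the right of its square, which choosing the highest genes made nearly certain.

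The 20 highest genes outside the mitochondrial and ribosomal protein genes ranged from 12.94 to 16.54. The others included PCBP1-AS1, which stood 10.16 log2 units above its partner PCBP1 (3.84 ± 0.06), ENO3, a muscle enolase, at 13.87 ± 0.25, PAQR3 at 13.78 ± 0.32, ATG10, an autophagy enzyme, at 13.64 ± 0.27, RPL30-AS1 at 13.47 ± 0.34 and MVP-DT at 13.34 ± 0.34. Of the 20 genes, 17 had a GENCODE 29 model, and all 17 share exonic bases with a protein-coding gene on the opposite strand. That partner had a value for 16 of them and was lower in 16 of 16, by a median of 9.40 log2 units and a range of 5.50 to 13.55. These gaps exceeded the SDs of both genes in each pair. Because the 20 genes were chosen for the highest values, a lower partner was nearly certain in advance. The count and the gaps are therefore a description and no test. The partners of ENO3, ATG10 and MVP-DT were the actin-binding gene PFN1 at 6.79 ± 0.10, the ribosomal protein gene RPS23 at 4.83 ± 0.09 and the transcription factor gene MAZ at 3.99 ± 0.02. The strand setting of the counting is not given in the sources used here, so it is uncertain, for every gene and list given here and not for overlapping genes alone, which strand's RNA a value measures.

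Genes annotated as antisense had a value in 2355 cases, with a median of 5.21, and held 42.8% ± 2.30 of the linear value (n = 2). Protein-coding genes had a value in 8431 cases, with a median of 2.99, and held 37.9% ± 0.279. Of the protein-coding genes that share exonic bases with an opposite-strand gene, 61.5% had a value, with a median of 3.95, against 32.5% and 2.33 for those that share none. The corresponding figures for antisense genes were 59.4% and 6.03 against 20.2% and 2.44. Antisense genes stood above the protein-coding gene of longest overlap in 931 of 1235 pairs with both values (75.4%), by a median of 2.87.

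In 4 of the fixed lists of genes that most cells express (cytosolic ribosomal proteins, translation factors, cytoskeleton and glycolysis), 70 genes have an opposite-strand partner, and both genes had a value in 43. The partner was higher in 33 of these 43 pairs (76.7%), and the median gap was 3.76. Only the partner had a value in 13 further pairs, only the list member in 11 and neither in 3. TPT1, GAPDH, VIM, TUBB, TUBA1B, RPS23 and PFN1 were among the 33. EIF4B, a translation initiation factor, stood at 5.29 ± 0.14 against 12.35 ± 0.17 for TNS2-AS1. In the other 10 pairs the list member was higher. Among them were RPS28 at 8.26 ± 0.11 against KANK3 at 2.22 ± 0.03, the myosin light chain gene MYL6 at 10.21 ± 0.19 against SMARCC2 at 5.22 ± 0.00, and RPL10 at 9.89 ± 0.11 against DNASE1L1 at 5.64 ± 0.02. The 38 ribosomal protein genes with a value and no opposite-strand partner had a median of 2.36, against 3.06 for all genes.

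Mast cell genes had values, most of them low. With the strand setting not given, these values need not measure the messenger RNA of the genes named. The granule list, which holds the tryptases and other granule proteases, had a value for 9 of 11 members and a median of 2.33. The granule protease genes CTSG and GZMB stood at 5.40 ± 0.06 and 3.48 ± 0.02, and the tryptase gene TPSB2 at 3.02 ± 0.01. Of the receptors, 9 of 15 had a value, with a median of 2.74, led by the lectin SIGLEC6 at 5.50 ± 0.01 and MRGPRX2, a receptor for basic secretagogues, at 3.92 ± 0.08. Transcription factors had a value for 11 of 12, with a median of 2.89, and included GATA2, a regulator of mast cell identity, at 9.03 ± 0.19 and STAT5B, which acts downstream of KIT, at 7.24 ± 0.16. Lipid mediator synthesis had 5 of 10 and a median of 1.81, with HPGD, a prostaglandin-degrading enzyme, at 6.36 ± 0.01. Signalling from the IgE receptor had 12 of 17 and a median of 3.67, with the phospholipase PLCG1 at 6.69 ± 0.22 and the phosphatase PTPN6 at 5.55 ± 0.01. Of the 46 mast cell genes with a value, 20 were detected and 26 lay below the threshold. Among the 26 were the granule genes TPSAB1, TPSB2, TPSD1, TPSG1, CMA1, CPA3 and HDC, the receptors KIT, MS4A2, IL1RL1, CSF2RB and ENPP3, the transcription factors GATA1, TAL1, RUNX1, LMO2, LMO4 and ZFPM1, the enzymes HPGDS, LTC4S, PTGS1 and PTGES3, and the signalling genes LYN, SYK and GRB2. Members with no value included SRGN and NDST2 (granule), FCER1A, FCER1G, SIGLEC8, C5AR1, HRH4 and ADORA3 (receptors), MITF (transcription factor), ALOX5, ALOX5AP, PTGS2, PLA2G4A and LTA4H (lipid mediators), and FYN, LAT, PLCG2 and VAV1 (signalling). Against random lists of detected genes these 5 lists lay at the percentiles 0, 0, 0, 0 and 0.04, and against all genes with a value at 18.8, 35.7, 40.1, 13.1 and 75.2, so that the low call ended with the wider background. SIGLEC6 lies opposite ENSG00000268777, whose value was 12.60 ± 0.15.

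Markers of other cell types had fewer values. Over 12 lists, 41 of 139 genes had a value (29.5%), against 46 of 65 mast cell genes (70.8%). The genes with a value had nearly equal median levels in both sets, 2.65 for the other cell types and 2.64 for mast cell genes. T cell markers had 1 of 12 (CD4, 1.02 ± 0.00), B cell markers 2 of 10 with a median of 2.76, monocyte and macrophage markers 3 of 14 with 2.29, neutrophil granule markers 2 of 10 with 1.48, and eosinophil and basophil markers 3 of 11 with 2.33. Colon epithelium had 3 of 16, among them the microvillus gene VIL1 at 7.47 ± 0.24. Fibroblast markers had 4 of 10 with a median of 1.84, endothelial markers 3 of 10 with 2.44 and hepatocyte and plasma protein markers 3 of 12 with 2.98. Megakaryocyte and platelet markers had 4 of 10 with a median of 6.93, led by THBS1 at 8.12 ± 0.10 and GP1BA at 7.72 ± 0.22. The erythroid list had 6 of 14 with a median of 3.04 (percentile 46.8 against all genes), and its haemoglobin gene HBA2 stood at 8.99 ± 0.50. Neuron markers had 7 of 10 with 2.65 (percentile 34.1).

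**Figure D2:**
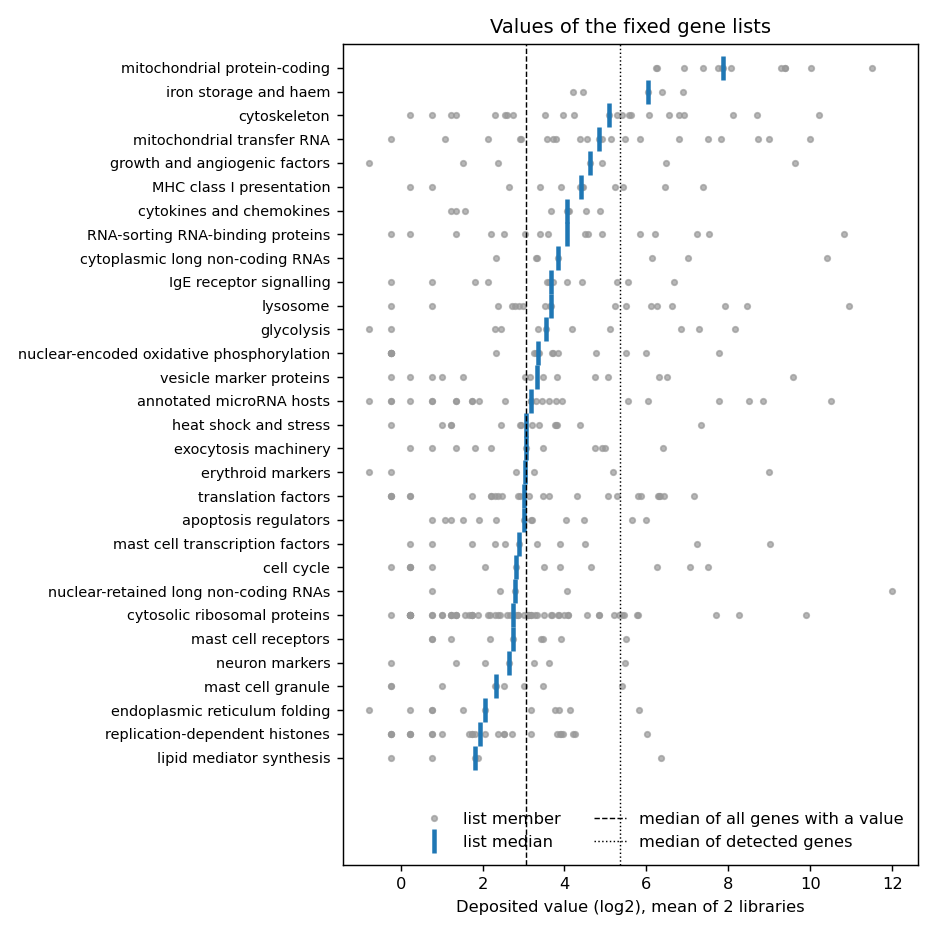
Mean deposited log2 value of each list member with a value (grey circles) and the list median (blue bars) for the lists with a percentile (olfactory receptors and small nucleolar RNAs not drawn), with lines at the median of all genes (3.06) and of detected genes (5.35). The mitochondrial protein-coding list has the highest median, 7.87.

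Of the 45 lists, 32 had enough members for a percentile. The mitochondrial protein-coding list was the one list above the 98th percentile against detected genes (13 of 13 members, median 7.87, percentile 99.7), and 25 lists were below the 2nd, where 94.5% of 200 simulated random lists with no shift were also set apart. Against all genes with a value 3 lists were above and 3 below, and 22 of the 25 low calls ended. The lists that kept a low call were replication-dependent histones (26 of 69, median 1.94, percentile 0.945 against all genes), olfactory receptors (97 of 855, 2.22, 0.06) and small nucleolar RNAs (14 of 472, 1.68, 1.57). The call for histones ended with members limited to detected genes (percentile 3.435), and that for small nucleolar RNAs ended after division by exonic length (73.85). Cytoskeleton genes (23 of 27, median 5.08) moved from the percentile 31.6 to 99.55, and mitochondrial transfer RNAs (21 of 22, 4.85) from 20.4 to 98.8. Percentiles given for the lists that follow are against all genes with a value, where none of them stood apart.

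Cargo and vesicle genes varied widely within their lists. Vesicle marker proteins had 14 of 19 with a median of 3.32 (percentile 62.8), led by VPS4A, an ATPase of vesicle scission, at 9.59 ± 0.01, and CD63, a tetraspanin, stood at 6.30 ± 0.06. RNA-binding proteins that sort RNA had 16 of 22 with 4.05 (89.3), led by HNRNPU at 10.82 ± 0.09 and HNRNPA2B1 at 7.52 ± 0.08. Exocytosis machinery had 11 of 17 with 3.06 (48.3), with SYT9 at 6.40 ± 0.07. Growth and angiogenic factors had 7 of 18 with 4.62 (88.8), with TGFB1 at 9.62 ± 0.01 and FGF2 at 6.48 ± 0.01. Cytokines and chemokines had 9 of 23 with 4.06 (82.4), with IL1B at 4.87 ± 0.16 and CCL4 at 4.53 ± 0.14. MHC class I presentation had 12 of 14 with 4.40 (91.7), with the peptide transporter TAP1 at 7.38 ± 0.15. Lysosomal genes had 18 of 25 with 3.66 (79.8), with the cathepsin CTSZ at 10.96 ± 0.13 and NPC2, a cholesterol carrier, at 8.46 ± 0.19.

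Cytosolic ribosomal proteins had 62 of 79 with a median of 2.75 (percentile 18.2) and held 0.117% of the linear value. Translation factors had 26 of 33 with 3.02 (46.5), glycolysis 11 of 19 with 3.55 (70.4), nuclear-encoded oxidative phosphorylation 17 of 41 with 3.37 (66.0) and iron storage and haem 5 of 13 with 6.03 (96.0). Endoplasmic reticulum folding had 11 of 16 with 2.07 (9.03), heat shock and stress 14 of 18 with 3.07 (49.5), cell cycle 13 of 27 with 2.82 (36.5) and apoptosis regulators 13 of 18 with 3.01 (46.3). Nuclear-retained long non-coding RNAs had 5 of 6 with 2.79 (40.8). Among these, KCNQ1OT1, an imprinted antisense transcript, stood at 12.00 ± 0.28. Cytoplasmic long non-coding RNAs had 7 of 13 with 3.84 (74.985), led by EPB41L4A-AS1 at 10.42 ± 0.13. MicroRNA host genes had 25 of 84 with 3.19 (57.0), led by MIR497HG at 10.51 ± 0.12. Structured small RNAs had 1 of 18 (RN7SL1, 3.62 ± 0.06), keratin-associated proteins 4 of 111 with a median of 2.63, and the mitochondrial ribosomal RNAs 2 of 2 with 4.55.

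The 2 libraries differed most at mitochondrial protein-coding and transfer RNA genes, which were higher in replicate 1. Both mitochondrial ribosomal RNA genes were slightly higher in replicate 2 (median log2 difference, replicate 2 minus replicate 1, 0.05). MT-RNR1 (3.55 ± 0.01) and MT-RNR2 (5.54 ± 0.06) stood at levels where differences are shrunken. Their SDs lay within the spread of genes from 2 to 4 (0.0369) and from 4 to 6 (0.0857), so no opposite direction is shown. All 13 mitochondrial protein-coding genes were higher in replicate 1, by a median of 2.14-fold (log2 difference, replicate 2 minus replicate 1, -1.10), which lay below all 10000 lists matched on level. MT-ND5, a subunit of complex I, had 12.43 in replicate 1 and 10.56 in replicate 2, a 3.67-fold ratio, and MT-ND4 10.85 and 9.20, a 3.14-fold ratio. The cytochrome b gene MT-CYB differed 2.91-fold, MT-CO3 2.87-fold and the transfer RNA gene MT-TY 2.70-fold. The share of linear value in the protein-coding list was 0.711% in replicate 1 and 0.235% in replicate 2. All 16 detected mitochondrial transfer RNAs were higher in replicate 1, by a median of -0.26 (percentile 0). Among all transfer RNA genes with a value, the 8 annotated on the minus strand had a median level of 7.66 and a median difference of -0.79, and the 13 on the plus strand a level of 3.78 and a difference of -0.10, where differences are more shrunken at the lower level. Of 21 lists with enough detected members, olfactory receptors had a median of -0.09 (percentile 1.58), with 17 of 28 members higher in replicate 1, and ribosomal proteins 0.07 (percentile 99.7), with 6 of 20 higher in replicate 1. Of 200 simulated random lists with no shift, 5.0% were set apart, with the differences shuffled over genes of all levels. At that rate about 1 of the 21 lists would be set apart. The rate for lists of related genes at their own levels was not estimated. Olfactory receptors were not recomputed at a linear value of at least 50, where too few members were left. The call for ribosomal proteins ended there (percentile 91.3).

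**Figure D3:**
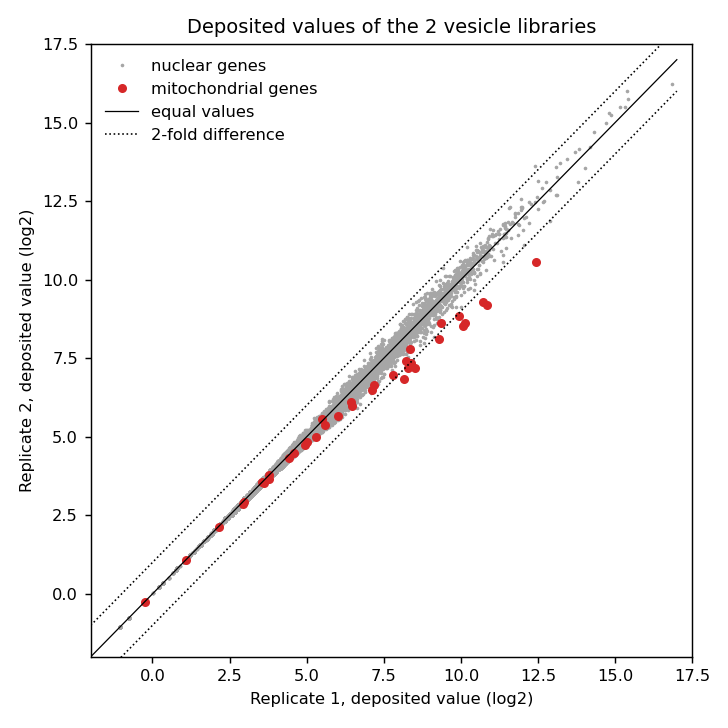
Deposited log2 value of each gene in replicate 1 (horizontal axis) and replicate 2 (vertical axis), with mitochondrial genes in red, the solid line at equal values and dotted lines at a 2-fold difference. The red point farthest to the right is MT-ND5, at 12.43 and 10.56.

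Across the 6576 detected genes, which are not independent replicates, Pearson's r was 0.996 and Spearman's rho 0.997. The replicate spread was 0.131 log2 units, the median difference was -0.02, and 0 genes had identical values. Shrinkage pulls the 2 values of a gene together, so r, rho and the spread overstate the agreement of the libraries. For means above 10 the spread was 0.248. A 2-fold difference was reached by 13 genes, 12 higher in replicate 1 and 1 in replicate 2, with no test behind the count. Of these, 11 were mitochondrial. The others were PDZD8, a lipid transfer protein gene, at 12.90 in replicate 1 and 11.87 in replicate 2, and ENSG00000290038, at 12.40 and 13.62. The largest difference of any gene was 0.131 log2 units for means from 2 to 4 and 0.542 from 4 to 6. Under this shrinkage the count of 2-fold genes says little about genes with means up to 6.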

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

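Chosen after seeing the data were the alternatives on strand and antisense genes, log2(value + 1) or (value + 5), detected list members, the median mitochondrial difference, and the count of 2-fold genes without mitochondrial genes or at 50. The others were planned. No paired analysis was possible because the series has 1 group. Thinning to equal depth, count-based size factors and the 0.1 pseudocount need counts and were not run. Scaling by library totals shifts all genes of a library alike, so it could not move a list percentile and says nothing there. Values for 24 list settings were not computed because too few members were left. The effect of depth was not tested. With other thresholds, 13438 genes had a linear value of at least 1 in both libraries and 2904 of at least 50, against 6576 at 10. Leaving out a replicate gave 6613 to 6727. The correlation was 0.9958 after adding 5, 0.9989 over all genes, 0.9877 at 50 and 0.9965 without mitochondrial and ribosomal protein genes, against 0.996. The spread was 0.0896 over all genes and 0.177 at 50. Without mitochondrial genes 2 genes differed 2-fold. Antisense genes held 38.4% without the 10 highest genes. The causes were not tested, except that the thresholds by construction take in more or fewer low, shrunken genes.

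List levels were recomputed 181 times: 140 kept their call, 38 lost it, 3 gained one and 0 reversed. Of the 140, 32 came from adding 1 before the logarithm, which nearly keeps the order of the genes and so could hardly move a percentile. Leaving out replicate 1 kept 31 calls and leaving out replicate 2 kept 32, where shrinkage had already pulled the libraries together. The count of kept calls therefore overstates how stable the levels are. The background decided most, by its construction. Against all genes with a value the low call ended for mast cell granule (18.8), receptors (35.7), transcription factors (40.1), lipid mediators (13.1), IgE signalling (75.2), vesicle markers (62.8), RNA-sorting proteins (89.3), exocytosis (48.3), ribosomal proteins (18.2), translation factors (46.5), oxidative phosphorylation (66.0), glycolysis (70.4), lysosome (79.8), reticulum folding (9.03), heat shock (49.5), cell cycle (36.5), apoptosis (46.3), nuclear (40.8) and cytoplasmic (74.985) long non-coding RNAs, erythroid (46.8) and neuron (34.1) markers and microRNA hosts (57.0). Cytoskeleton (99.55) and mitochondrial transfer RNA (98.8) gained a high call. With members limited to detected genes the low call ended for transcription factors (22.7), IgE signalling (7.07), vesicle markers (39.2), RNA-sorting proteins (51.7), exocytosis (35.8), ribosomal proteins (20.1), translation factors (71.4), glycolysis (41.35), lysosome (79.3), cell cycle (51.65), histones (3.435) and microRNA hosts (67.9). Divided by exonic length it ended for cytoplasmic long non-coding RNAs (4.89), erythroid markers (4.18) and small nucleolar RNAs (73.85), and mitochondrial transfer RNA rose to 100. Without replicate 1 cytoplasmic long non-coding RNAs lay at 2.245, where the low call ended, and without replicate 2 at 1.165. Of 8 list differences recomputed at 50, 7 kept their call, and ribosomal proteins lost theirs (91.3).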

Other observations

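The tests in this part were chosen after the values were seen, except the percentile of the mitochondrial list among lists matched on level, which was planned and is read here against an explanation framed afterwards. High values at genes opposite members of the vesicle, lysosome and cytokine lists were not described above. PRADX stood at 12.91 ± 0.29 (n = 2) opposite the lysosomal protease gene CTSD at 5.24 ± 0.10, and MIF-AS1 at 12.13 ± 0.25 opposite the cytokine gene MIF at 3.67 ± 0.02. ENSG00000267112 stood at 11.80 ± 0.10 opposite RAB27B, a GTPase of vesicle release, at 0.76 ± 0.01. VPS4A and its partner COG8 were alike, at 9.59 ± 0.01 and 9.66 ± 0.25.

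Most of the highest values fell at genes with a partner on the opposite strand, such as GAPDH, FTH1 and VIM. That the partner was lower was nearly fixed by choosing the highest genes. The abundance of the partners in cells was not tested, and 2 of the 20 highest genes had no annotated position. A library that does not mark strand would leave ribosomal protein genes without a partner at a high rank, if vesicles hold their messenger RNA abundantly. The 38 such genes lay at the percentile 4.55 among random lists of all genes. That argues against such a library only under this assumption, which was not tested. Counting the reads of a strand-marking library on the opposite strand may account for the pattern. The partner was higher in 76.7% of 43 pairs from 4 lists. That share includes TPT1, GAPDH, VIM, TUBB, TUBA1B, RPS23 and PFN1, whose pairs were among those that prompted the explanation. No share without them was computed. Over all antisense genes, 931 of 1235 stood above the protein-coding gene of longest overlap (75.4%), and some of the prompting pairs are among these too. The labels do not state whether the kit marks strand, and 10 of the 43 pairs went the other way, RPL10, MYL6 and RPS28 among them. Antisense RNA carried by the vesicles stays open. The pairs cannot tell it apart from opposite-strand counting, because the median gap of 3.76 log2 units would arise either way. Values of the other strand were not analysed here. Antisense RNA would not by itself lower the 38 genes without a partner (median 2.36, against 3.06 for all genes). Their true level in vesicle RNA is not known, so those values do not decide the question.

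Mitochondrial protein-coding genes were higher in replicate 1 by a median of 2.14-fold. Both mitochondrial ribosomal RNA genes were slightly higher in replicate 2, within the spread of genes at their levels. A scaling difference left after normalization would move all genes of a level alike. The median difference was -0.0198 log2 units over all detected genes and 0.0349 in lists matched on level. That argues against such a remainder as the cause. Normalization by itself brings the median near 0, so the scaling of the libraries before it was not tested. Larger differences at high levels under the transform would appear in lists matched on level, and the mitochondrial list lay at the percentile 0 of those. No biological explanation was tested, since the design names no difference between the replicates, and a difference in vesicle collection stays open.

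If values belong to the opposite strand, genes opposite mast cell transcripts should have values more often than genes opposite markers of other cell types. The partner had a value for 9 of 10 mast cell genes with an annotated partner, with a median of 8.88. It did for 7 of 24 genes of the 12 other lists, with a median of 2.21. The difference of 60.8 percentage points was not tested. Among all genes that share exonic bases with an opposite-strand gene, 61.5% of protein-coding and 59.4% of antisense genes had a value. Of the 9 partners 5 reached 8, such as CACNA1H at 11.11 ± 0.29 opposite the tryptase gene TPSG1 and C5orf58 at 9.89 ± 0.23 opposite LCP2, and the lower ones were those of CMA1 (4.06 ± 0.03), PLCG1 (4.39 ± 0.11), GFI1B (2.74 ± 0.04) and LTA4H (2.74 ± 0.04). Mast cell RNA read on the opposite strand would give such a difference, but the counts do not by themselves separate the strands. Same-strand values were also present for a larger share of mast cell genes than of the other lists (70.8% against 29.5%). Of all annotated protein-coding genes, 42.3% had a value. The count rests on 10 mast cell genes.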
